A study of Homo sapiens with 2 samples.

How the data were processed

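ADAR1 binding to RNA was mapped by crosslinking, immunoprecipitation and sequencing (CLIP-seq) in U87MG, an established human glioblastoma (astrocytoma) cell line. Per the labels' protocols, cells were irradiated with ultraviolet light on ice, RNA linked to ADAR1 was pulled down with a mouse monoclonal antibody, and linkers were joined to both RNA ends. Per the labels' protocols, the linked RNA was then amplified by PCR for 23 cycles, and products of 75 to 250 bases were selected on a gel. The series holds 2 libraries, 1 labelled AB1 and 1 labelled AB2 for the antibody. The study's description speaks of different monoclonal antibodies, while both libraries carry the same antibody catalogue entry in their labels, so whether the antibodies differed is left open here.

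The authors deposited 1 list of 23782 clusters for the whole series, with chromosome, start, end, strand and a class, Alu or non-Alu, for each cluster. Other fields of the deposited list hold no measurement: the fifth column repeats the position of every cluster. The list has no tag number, score or p-value, and no column separates the 2 libraries. The sequencing depth behind each cluster and each library is therefore unknown, and no comparison between AB1 and AB2 could be made. Per the submitters' processing notes, adapters were handled with cutadapt 1.1, reads were aligned with Novoalign 2.08.22, and the genome build was hg19. The cluster caller, its thresholds, whether and how the libraries were combined and the way the Alu class was assigned are not given in the sources used here. These steps can change what is counted: how reads with several matching places were treated decides which copies of a repeat are listed, and the rule for joining reads sets the lengths of the clusters and the gaps between them.

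The build was checked against the annotation at hand, GENCODE release 29 on GRCh38. In the list, 218 clusters on 12 chromosomes lay beyond the last GRCh38 gene of their chromosome, 70 of them on chromosome 9, so the coordinates were not used with that annotation. No hg19 genome or gene annotation was used here. Clusters are therefore named by hg19 position and not by gene, and 15 gene lists, the gene features, microRNA precursors, untranslated regions and sequence words planned before the data were examined were not analysed here. GENCODE gave only the number of protein-coding genes on each chromosome. Positions are printed counting from 1, reading the starts in the list as counted from 0 as in a BED file. The list does not state this, so a start may be off by 1 base.

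Clusters were analysed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Shares are given with the standard error over 1000 bootstrap draws of blocks of 5 Mb, which covers the variation along the genome and not the variation between libraries, or with a Wilson 95% interval, which covers counting error only. A neighbour was a cluster on the same strand whose nearest edge was within 1000 bases. The share of clusters with a neighbour was set against 1000 random placements of the clusters, each keeping its length and strand, between the first and last cluster of its chromosome (one-sided permutation test). A second set of 1000 placements, chosen after the data were seen, moved each cluster by at most 500 kb. Alu and non-Alu labels were compared by permuting the labels within chromosomes, 10000 times for lengths and 1000 times for neighbours (two-sided). In the alternative settings the label permutation for neighbours was one-sided. Strands were permuted within chromosomes 1000 times (one-sided). The smallest p-value is 0.001 with 1000 permutations and 0.0001 with 10000. P-values of a family were adjusted by the Benjamini-Hochberg method. Clusters are not independent replicates, and no p-value here measures the spread between cultures or antibodies.

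The rule for the regions to name, set before the data were examined for the case without a usable annotation, was the 10 windows of 100 kb with the most clusters. Because 4 windows tied at 12 clusters, 11 windows are named. The 5 longest clusters, the second window by Alu clusters, and the regions named in the closing section were chosen after their values were seen. The procedures were tested on simulated data with the real number of clusters. All of 1000 planted neighbours were recovered (100%). Strand agreement within 10 kb was 99.9% with planted strand domains and 50.2% with random strands. These values follow from how the data were simulated, so they check the code and not the choice of random placement. Alternatives were a length filter at the median, merging clusters within 50 bases, a shorter neighbour distance, placement near the original position, and leaving out dense windows or repeated regions.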

Results

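ADAR1 is an enzyme that converts adenosine to inosine in double-stranded RNA, and CLIP-seq was used to find the RNA it touches in U87MG glioblastoma cells. The deposited list, given for the whole series of the AB1 and AB2 libraries, 1 for each antibody label, held 23782 clusters on 24 chromosomes. No cluster lay on the mitochondrial genome. The clusters covered 4505988 bases of hg19 in all. They divided almost evenly between the strands, with 11896 on the plus strand and 11886 on the minus strand. Because the list has no tag counts and no separate columns for AB1 and AB2, the values below have no replicates and no measured depth.

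The first question was which RNA sequences ADAR1 contacted. Most clusters lay in Alu repeats, the primate retrotransposons whose inverted copies can fold into double-stranded RNA. The authors' labels put 20200 clusters, 84.9% ± 0.55 (standard error over 5 Mb blocks), in the Alu class. The remaining 3582 clusters, 15.1% ± 0.55, were non-Alu. The Wilson 95% interval of the Alu share was 84.5 to 85.4%. The share of Alu sequence in the transcripts of these cells was not measured here, so no enrichment over background can be given.

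Alu and non-Alu clusters had nearly the same typical length and differed at the extremes. The median was 193 bases for Alu clusters (standard error over blocks 0.53) and 191 bases for non-Alu clusters (standard error 1.1), a difference that did not pass the test (label permutation, adjusted p = 0.197). Non-Alu clusters were more often long: 52 of them, 1.45%, exceeded 400 bases, against 17 Alu clusters, 0.084%. Non-Alu clusters were also more often short, with 0.865% under 40 bases against 0.218% of Alu clusters. Both differences reached the smallest p-value that the permutations allow (label permutation, p = 0.0001 before adjustment). The 5 longest clusters were all non-Alu. The longest, of 1509 bases, lay on the minus strand of chromosome 11 from 62294933 to 62296441. The next, of 1122 bases, lay on the minus strand of chromosome 16 from 30234835 to 30235956. Another of 944 bases followed it on the same strand, from 30235962 to 30236905.

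**Figure D1:**
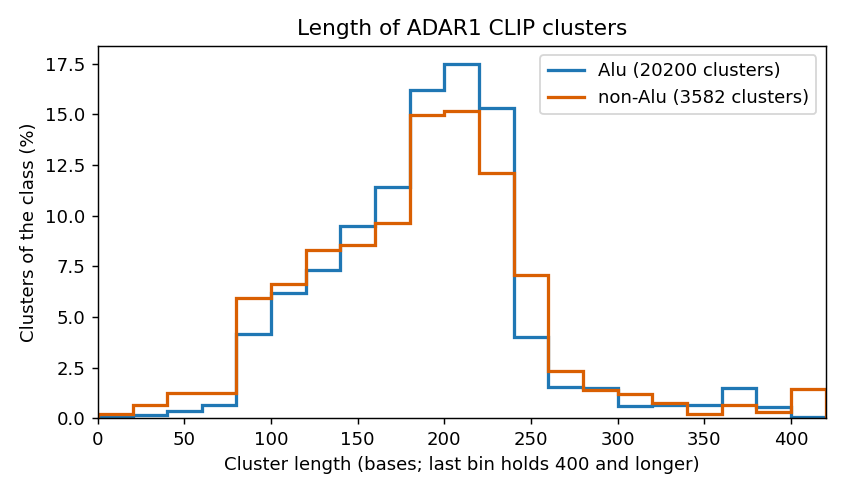
Length of Alu and non-Alu clusters, in bases on the horizontal axis, as the percent of the clusters of each class in bins of 20 bases; the last bin holds 400 bases and longer. Both classes peak near their medians of 193 and 191 bases, and non-Alu clusters make up more of both ends.

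Alu clusters were the majority on each chromosome. The Alu share was lowest on chromosome 20 (80.4% ± 3.0, standard error over blocks, 566 clusters). It was 92.2% ± 1.2 on chromosome 18 (476 clusters), 89.3% ± 1.9 on chromosome X (910 clusters) and 93.2% on chromosome Y, where only 73 clusters were listed (Wilson interval 84.9 to 97.0%). Of these 73, 29 overlapped a same-strand chromosome X cluster at an offset of 50000 bases, so they may repeat chromosome X clusters (see the closing section). The spread of the Alu share between chromosomes was 1.12 times that obtained when the 5 Mb blocks were reassigned to chromosomes at random, and this did not pass the test (permutation test, p = 0.353). Chromosome 1 had the most clusters, 2291.

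**Figure D2:**
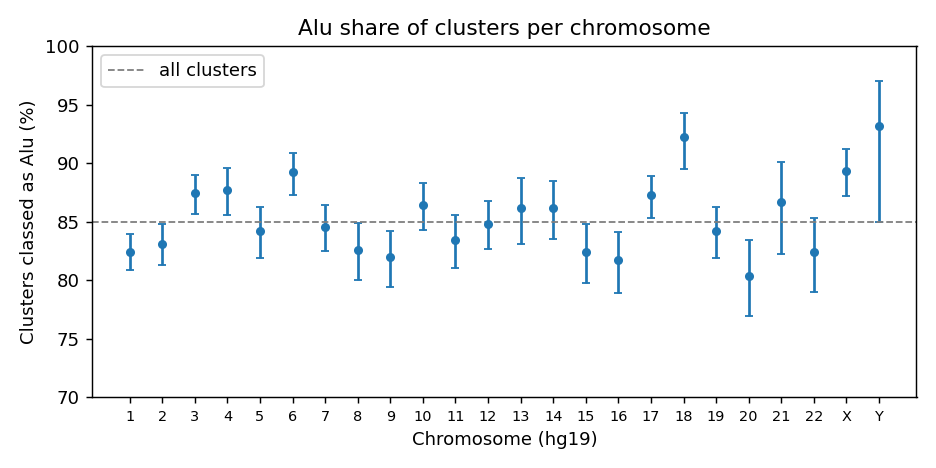
Percent of clusters classed as Alu on each chromosome, with Wilson 95% intervals as error bars; the dashed line marks the share over all clusters, 84.9%, and the vertical axis starts at 70%. Values range from 80.4% on chromosome 20 to 93.2% on chromosome Y. The bars cover counting error only and not variation along a chromosome, so bars that miss the dashed line do not show that chromosomes differ.

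Cluster numbers followed the number of protein-coding genes that GENCODE release 29 lists on a chromosome, in both classes. Across the 24 chromosomes, Pearson's r was 0.89 for Alu clusters and 0.88 for non-Alu clusters, and Spearman's rho was 0.87 and 0.83. Permutation p-values were at or near the smallest that 100000 resamples give (adjusted p = 3e-05 for both r values, 3e-05 and 4e-05 for the rho values, 4 relations tested). Without chromosomes 1 and Y, the farthest from the median gene number, r was 0.81 for Alu and 0.76 for non-Alu clusters. Chromosome 19, the gene-dense chromosome rich in zinc finger genes, had the fewest clusters per protein-coding gene, 0.728. Chromosome 11 had 0.807 clusters per gene. Chromosomes 13 and 18, which are gene-poor, had 1.82 and 1.77 clusters per gene. Chromosome length was not taken into account in the correlations, and gene length was not taken into account in these ratios.

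Most clusters of both classes had no close neighbour, but non-Alu clusters had one more often than Alu clusters. A non-Alu neighbour on the same strand within 1000 bases was found for 543 of 3582 non-Alu clusters, 15.2% ± 1.2 (standard error over blocks). When the class labels were permuted among the clusters of each chromosome the value was 1.25% ± 0.26 (SD), so the observed share was 12.1 times the permuted one. Alu clusters had an Alu neighbour in 4.51% ± 0.22 of cases, against 5.80% ± 0.11 (SD) under permuted labels. Both label permutation tests reached the smallest value possible (adjusted p = 0.001), but the permuted labels share the same positions, so the lower Alu value mirrors the non-Alu excess and is no separate finding. Counting neighbours of either class, 17.1% ± 1.2 of non-Alu and 4.86% ± 0.23 of Alu clusters had one, a difference of 12.2 percentage points (label permutation, adjusted p = 0.001). The 12.1-fold value therefore joins how often non-Alu clusters had any neighbour with how often neighbours shared a class. Permuted labels do not keep clusters of one place or transcript together. These tests thus cannot show crowding beyond clusters that share a transcript and its class.

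Clusters of both classes were nonetheless closer together than random positions. Random positions can fall outside transcripts and, for Alu clusters, outside Alu repeats, where clusters of that class would not be expected. The excess below is therefore no measure of crowding within transcripts. Over all clusters, 1593, or 6.70% ± 0.31, had a neighbour, against a mean of 1.05% when the clusters were placed at random along their chromosome (6.36-fold, permutation p = 0.001). The excess was 2.82-fold when clusters were moved by at most 500 kb. In that second setting it was 2.31-fold for Alu clusters near Alu clusters and 10.1-fold for non-Alu clusters near non-Alu clusters (permutation p = 0.001 for each). The gap between neighbours of the same class had a median of 260.5 bases over 328 non-Alu pairs and 456.5 bases over 464 Alu pairs.

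The densest regions of the genome were non-Alu. Of the 11 windows of 100 kb with 12 or more clusters, 10 held more non-Alu than Alu clusters and 7 held no Alu cluster. The highest count was 26, in the window of chromosome 11 that starts at 62200001, all non-Alu and all on the minus strand. They lay between 62285661 and 62300099 and covered 54.8% of that stretch. The window held 26 clusters against a maximum of 12 in any window over 1000 random placements along the chromosomes (permutation p = 0.001). The maximum was 15 when clusters were moved by at most 500 kb (permutation p = 0.001). Both placements ignore transcripts, so they do not show how unusual the window is among transcribed regions. On chromosome 2, 22 minus-strand clusters, 21 of them non-Alu, lay between 216236580 and 216296732. Another 16, all non-Alu and on the minus strand, lay between 238232835 and 238293639. On chromosome 15, 12 plus-strand non-Alu clusters fell within 10261 bases from 43813583 to 43823843 and covered 29.5% of them, while 12 on the minus strand were spread from 48707785 to 48797356. On chromosome 8, 13 minus-strand non-Alu clusters lay between 144940327 and 144999783.

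The other dense windows included some with both classes. Chromosome 12 had 16 plus-strand clusters from 66218307 to 66283668, 13 non-Alu and 3 Alu. Chromosome 7 had 12 on the plus strand from 128400066 to 128498846, 9 non-Alu and 3 Alu. Chromosome 1 had 14 non-Alu clusters on the plus strand from 145313510 to 145362494, and 13 from 144811838 to 144879463, of which 10 were on the plus and 3 on the minus strand. The exception among the 11 was chromosome 10, where 12 minus-strand clusters from 75214743 to 75292918 were all Alu and covered 2.51% of the stretch. The only other window with 10 or more Alu clusters was on chromosome 19, with 10 on the minus strand from 2520020 to 2597845. The 11 windows together held 149 non-Alu clusters, 4.16% of that class. Windows with 3 or more non-Alu clusters numbered 241 and held 29.7% of the class, against 5.19% ± 0.59 (SD) with permuted labels (permutation test, adjusted p = 0.001). Here too, permuted labels do not keep clusters of one transcript together, so crowding beyond shared transcripts is not shown. Genes at these positions were not assigned.

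**Figure D3:**
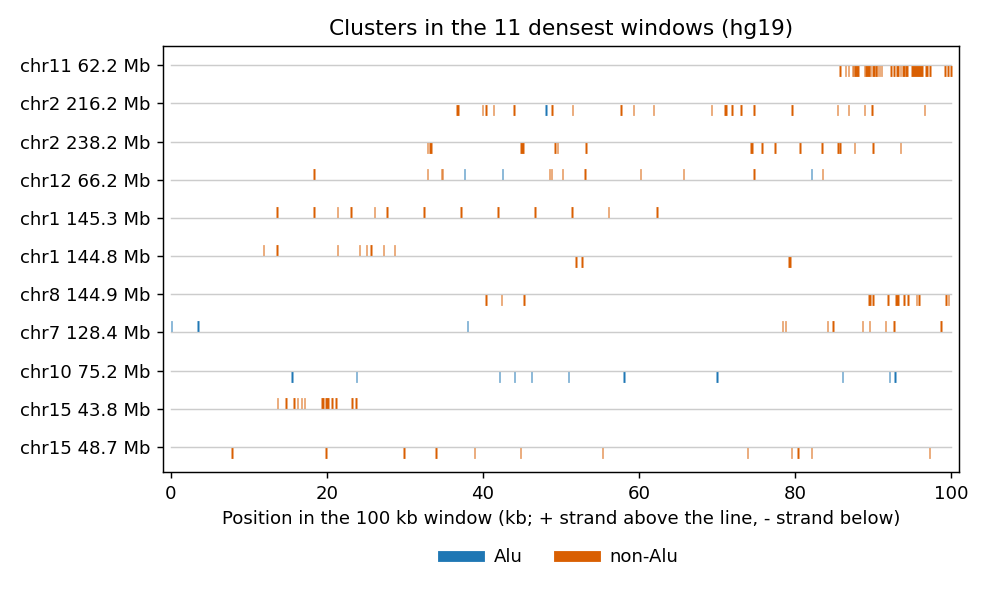
Positions of clusters, in kb from the window start, in the 11 windows of 100 kb with the most clusters, Alu in blue and non-Alu in orange, plus strand above and minus strand below each line. The chromosome 11 window packs its 26 non-Alu clusters into 14439 bases, and the chromosome 10 window spreads its 12 Alu clusters over 78176 bases.

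Nearby clusters mostly lay on the same strand of the genome. Of 5265 pairs of consecutive clusters with midpoints under 10 kb apart, 94.6% ± 0.38 (standard error over blocks) were on the same strand, against 50.1% ± 0.71 (SD) with permuted strands (permutation p = 0.001). The agreement declined with distance, to 87.8% ± 0.64 at 10 to 20 kb, 70.7% ± 0.83 at 50 to 100 kb and 55.4% ± 1.2 at 200 to 500 kb. Beyond 500 kb it was 51.7% (Wilson interval 48.8 to 54.6%). Of 703 windows of 100 kb with 5 or more clusters, 417, or 59.3%, held clusters of a single strand. With permuted strands the share was 4.41% ± 0.75 (SD) (permutation p = 0.001). CLIP reads keep the strand of the RNA, so clusters of the same transcript share a strand. Permuted strands do not keep transcripts together, so neither test shows anything particular to ADAR1.

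Strand agreement differed with the classes of the pair and with distance. Under 1 kb, 291 of 292 non-Alu pairs were on the same strand (99.7%, Wilson interval 98.1 to 99.9%), while Alu pairs reached 86.0% (82.5 to 88.9%, 449 pairs) and mixed pairs, of an Alu and a non-Alu cluster, 96.4% (87.9 to 99.0%, 56 pairs). Of the 63 Alu pairs on opposite strands, 59 overlapped. Without these, 99.0% of 390 Alu pairs agreed (97.4 to 99.6%), a setting chosen after the data were seen. The list holds 0 overlapping pairs on the same strand. Leaving out overlaps therefore removes only opposite-strand pairs and raises the agreement by construction. From 1 to 10 kb, non-Alu pairs differed from Alu pairs by -0.13 percentage points (95% bootstrap interval -2.67 to 1.74). Pooled under 10 kb, mixed pairs agreed in 88.9% ± 1.2 of cases, against 95.1% ± 0.42 for Alu pairs. The difference was -6.15 percentage points (95% bootstrap interval -8.71 to -3.74). At 1 to 10 kb alone, mixed pairs differed from Alu pairs by -8.01 points (interval -10.6 to -5.63). Among clusters at or above the median length the pooled difference was -1.61 points, with an interval of -5.74 to 1.86 that includes 0.

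**Figure D4:**
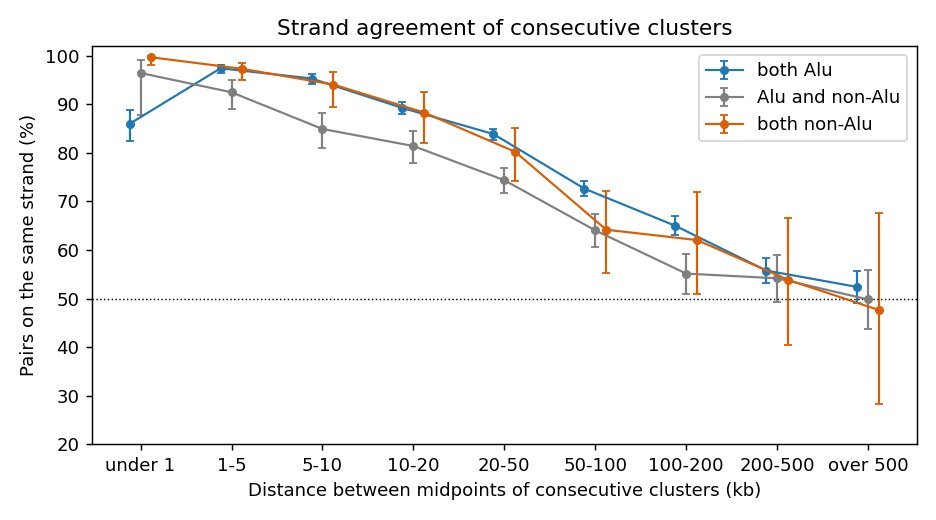
Percent of consecutive cluster pairs on the same strand by the distance between their midpoints in kb, for Alu pairs, non-Alu pairs and mixed pairs, with Wilson 95% intervals; the dotted line marks 50% and the vertical axis starts at 20%. Agreement falls from above 90% at 1 to 5 kb to near 50% beyond 500 kb, and Alu pairs under 1 kb, with the overlapping ones included, lie lower, at 86.0%.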

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

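Before the data were examined, the length filter was fixed for cluster number, length, Alu share and the spacing of all clusters, merging for the first 3 of these, and the neighbour distance of 200 bases for the spacing of all clusters. Every other alternative here was chosen after the data were seen. Of 38 alternative values, 33 kept their direction and their side of the test or, for number, length and Alu share, stayed within a set range, which for the Alu share was the Wilson interval of 84.5 to 85.4%. Keeping only clusters at or above the median length left 12119 clusters with a median of 221 bases, by construction, and an Alu share of 85.4%, just above that interval but inside the wider block interval of 83.8 to 85.9%. Under the same filter, the strand difference between mixed and Alu pairs shrank from -6.15 to -1.61 percentage points and no longer excluded 0; the cause was not tested, and the filter leaves fewer pairs. Without the 11 densest windows, which are mostly non-Alu, the Alu share was 85.5%, also above the first and inside the second. The share of non-Alu clusters with a non-Alu neighbour ranged from 6.48% (neighbour within 200 bases) to 15.2% and stayed above permuted labels in each setting (one-sided permutation p = 0.001). The share of all clusters with a neighbour ranged from 2.03% (within 200 bases) to 6.71% and stayed above random placement in each setting (permutation p = 0.001). Strand agreement within 10 kb ranged from 94.4 to 95.8%. The highest value was without the overlapping opposite-strand pairs, a setting that itself removes disagreeing pairs. No paired analysis was possible because each antibody label has 1 library and the list does not separate them. For the same reason no library could be left out. Alternatives listed beforehand that need genes, Alu matches, sequence or a score (placement within a gene, strand ignored, transcript choice, match length, partner distance, matching of gene lists, microRNA distance and word length) were not run, since no hg19 genome or annotation was used here. With no tag counts, the depth behind a cluster is unknown, and neither weak clusters nor places without a cluster can be judged.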

Other observations

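All tests in this part were chosen after the data had been seen, and some were added after a first version of the test had given its value.

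Alu clusters also occurred on both strands of the same place. In 59 pairs, on 20 chromosomes, clusters on opposite strands overlapped, by a median of 152 bases. Both members were Alu in each of the 59 pairs, which make up 0.584% of Alu clusters. Only 18 further opposite-strand pairs, of any class, lay apart by up to 1000 bases.

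Some clusters recurred at the same spacing elsewhere. Non-Alu clusters on chromosome 2 at 97859053 and 97864658 recurred at 97862788 and 97868393, with a distance of 5605 bases in both places. On chromosome 19, non-Alu clusters at 50610272 and 50615626 recurred at 50620978 and 50626332, 5354 bases apart each time. In the dense chromosome 1 window from 145300001, the starts of 11 non-Alu clusters longer than 200 bases were separated by 4656 to 4768 bases in 9 of 10 cases, and by 6245 bases in the other. Starts on chromosomes X and Y differed by exactly 50000 bases in 13 cases, while no other difference occurred more than 2 times.

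For the overlapping opposite-strand pairs, chance stays open: placement within 500 kb gave a mean of 73.0 overlaps and at most 109 against the 59 observed, but also 132.3 pairs apart by up to 1000 bases instead of 18. Overlaps made up 76.6% of the 77 opposite-strand pairs within 1000 bases, against 15.9% for uniform positions. Uniform positions are no fair comparison if Alu clusters can lie only at repeat units. The rule for that class is unknown, so this share decides nothing. Reads put on the wrong strand whatever their class would give pairs with a non-Alu cluster at about the 15.1% share of that class, but there were 0 of 59, with an upper 95% limit of 6.06%. A hypothesis is that both strands are transcribed there. Among 33 pairs with at least 2 other clusters within 50 kb, these lay on both strands in 63.6%. The exact 95% interval was 45.1 to 79.6%. The share was 22.9% around other Alu clusters and 21.3% at equal numbers of flanking clusters. Chance overlaps would also arise where clusters of both strands lie close, so this difference does not separate the hypothesis from chance. Reads placed at a wrong Alu copy stay open, since alignments were not used here.

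For the repeated spacing, 29 of the 45 chromosome Y clusters in its first 2.7 Mb, or 39.7% of all 73 on that chromosome, overlapped a same-strand chromosome X cluster at the offset of 50000 bases, which was picked from these same clusters. Among the 32 whose start has no match at the offset, 16 overlapped, against at most 3 at 996 other offsets, which is consistent with reads shared between the identical ends of X and Y. Over the genome, 13 matches between pairs of clusters spanning up to 10 kb had the same distance and lengths (within 2 bases), but 5 of them share clusters of 1 chromosome 2 array and 1 lies at the X and Y offset. With that array counted as 1 group and the X and Y match left out, there were 8 groups without a shared cluster. In 100 lists with shifted starts the mean was 1.75 and the maximum 5. The span of 10 kb and the grouping were chosen after the data were seen. These counts therefore do not decide against chance, for the set or for any single match. The 19 matches up to 100 kb did not exceed the highest of 19, a count that decides nothing for the 6 longer ones, of which 4 lie at the X and Y offset and 1 in the chromosome 19 array.

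For the crowding of non-Alu clusters, a continuous signal split into pieces stays open. Of the 328 gaps between non-Alu neighbours, 14.0% (exact 95% interval 10.5 to 18.3%) were of 50 bases or less, close to the 13.4% of Alu gaps, but the unknown rule for joining reads could have removed short gaps. Without the 11 densest windows, 13.3% of non-Alu clusters had a non-Alu neighbour, 12.1 times the value under permuted labels (one-sided permutation p = 0.001). These windows held only 149 non-Alu clusters, while 543 had such a neighbour, so leaving them out could not have ended the pattern. Whether a larger set of places carries it stays open. A candidate explanation that also stays open is the abundance of some transcripts in these cells, since no RNA level was used here, and no biological explanation was tested.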
